A study of Mus musculus with 2 samples.

How the data were processed

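The series holds 2 sequencing libraries from E14 cells, a male mouse embryonic stem cell line. The cells were grown without feeder cells on gelatin in medium with leukaemia inhibitory factor, per the labels' protocols. One library was made from chromatin immunoprecipitated with an antibody to Zic3 (ChIP). The other was made from chromatin that went through no antibody (input) and serves as the background. Cells were cross-linked with formaldehyde and chromatin was sheared by sonication before precipitation, per the labels' protocols. Both libraries were read from 1 end of each fragment. The group of each library was taken from its label, and there are 1 ChIP library and 1 input library, so no comparison has a replicate. The tests of peaks and windows compare the reads of these 2 libraries, not a condition. Intervals cover counting error or the spread between peaks, bins or chromosomes of these 2 libraries, and no interval covers an error between cultures. Tags from libraries amplified by PCR are not independent molecules.

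The authors deposited the aligned tags of each library, 1 line per tag with its position and strand, and a list of peaks. The genome build is mm8, per the submitters' processing notes. The aligner and its settings are not given in the sources used here. No tag shared its position and strand with another tag of its library, so repeats had been removed or collapsed before the authors deposited the tags. Peaks were called with MACS, a program that looks for local excess of ChIP tags over a Poisson background, per the file headers. Its version is not given in the sources used here. The call used the ChIP library against the input library with a p-value threshold of 1e-05, a band width of 300 bp, a model fold of 32, a tag size of 25 bp and an effective genome size of 1.87e+09 bp, per the file headers. The deposited tags were 35 bp long, so the tag size given to the program differed from theirs. Local background was taken from the peak region and from 1000, 5000 and 10000 bp around it, and the fragment length was estimated at 106 bp, per the file headers. The header states 12923076 input tags, and the deposited input tags number 12923077.

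For each peak the deposited list gives the count of ChIP tags, a score, a fold and a false discovery rate. The tag count is the authors' own raw count per peak, per the file headers. The score is minus 10 times the log10 of the p-value of the peak caller, per the file headers, and the deposited scores ran from 50 to 3100. The fold was read here as the ratio of ChIP tags to the local background of the peak caller. The false discovery rate is a percent, read here as obtained by the authors' peak caller through exchanging ChIP and input. The settings in the file headers do not state how either was computed. Peak scores and folds of the list are the authors' and were used here only to describe, rank and split the peaks. Positions are mm8 and count from 1.

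The strand shift of each library was the distance between plus-strand and minus-strand 5′ ends with the most pairs over the autosomes, between 50 and 400 bp, after smoothing over 11 bp. The 5′ end of each tag was moved by 58 bp towards the middle of its fragment, a distance taken from the ChIP shift. Tags were counted within 200 bp on either side of the deposited summit. Each peak was tested with a 2-sided exact binomial test of its ChIP tags among the tags of both libraries, against the share given by the library totals, with Benjamini-Hochberg adjustment over all peaks. The fold of ChIP over input is the ratio of tags per library total with 0.5 tag added to each count, and its interval is the exact 95% interval without that addition. Against 0 input tags the lower limit of that interval is given. The same test was run on every 200 bp window of the genome with at least 1 tag, without the peak list, with an adjusted p under 0.05 and at least a 5-fold difference as the threshold. The background was measured in the same way 10 kb downstream of each summit, where no peak lay nearby, and again at all such positions. Peaks per chromosome were divided by the input tags of the chromosome, and afterwards by its ChIP tags, and given with exact Poisson intervals. Intervals of ratios between sets of bins or peaks come from 1000 bootstrap draws. The spacing of summits was compared with 100 random sets of input tag positions on the same chromosomes.

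The per-peak test was tested on simulated data. Counts were drawn for the 23918 peaks from the input counts, with 200 peaks raised by a known fold. It recovered 0% of the peaks raised 2-fold, 54.0% of those raised 5-fold and 85.5% of those raised 10-fold. It made 0, 2 and 1 false calls in these draws. These shares hold for a list in which few peaks are raised, where the adjustment is stricter than for the deposited peaks. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

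The tests, the thresholds, the main alternatives and the rule for naming peaks were fixed before the data were examined. The rule names the 15 peaks with the largest deposited fold that also have an adjusted p under 0.05 and at least 5-fold more ChIP, and the 5 peaks with the lowest fold over input. Any other peak or region named was chosen after its values were seen. The test on 10 Mb segments of chromosome 19 was set before its values were seen, and the use of segments for the other chromosomes followed from it. Alternatives changed the window, the scaling of the libraries, the added tag, the movement of tags, the set of peaks and the background. The planned comparisons with genes, gene lists and sequence motifs were not run. The gene table used here is of assembly GRCm38, positions were not converted between builds here, and no sequence of mm8 was used here. Peaks are therefore given by position, and what gene or gene part lies there was not analysed.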

Results

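Zic3 is a zinc finger transcription factor of the Zic family that is expressed in mouse embryonic stem cells. The series asks where in the genome Zic3 binds in these cells. ChIP-seq measures this by sequencing DNA fragments that an antibody to the factor brings down from cross-linked chromatin. Fragments of the input, which saw no antibody, show how often each region is sequenced without selection. One ChIP library of 15750743 tags was compared with 1 input library of 12923077 tags from E14 cells. In both, 0 tags repeated a position and strand. Plus-strand tags made up 49.9974% of the ChIP library, with a Clopper-Pearson 95% interval of 49.9727 to 50.0221%, and 50.0039% of the input, with an interval of 49.9767 to 50.0312%. There was no replicate of either library, so no value below has an error between cultures.

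ChIP tags gathered on either side of the deposited summits, on opposite strands. Plus-strand 5′ ends were densest 60 bp before the summit and minus-strand 5′ ends 60 bp after it. After tags were moved by 58 bp, ChIP density at the summit was 14.9 times that beyond 1500 bp. The peak caller placed the summits from these same tags, so the height and the width of this profile depend on that placement. Input density was also highest at the summit, at 1.65 times that beyond 1500 bp. Over the genome, the strands of the ChIP library were shifted by 117 bp, with an SD of 2.97 bp over 19 autosomes. The shift was 126 bp in the input, with an SD of 18.2 bp and a range of 68 to 135 bp over the autosomes. The difference between the libraries was smaller than the spread of the input between chromosomes. The number of tag pairs at the best shift was 1.94 times that at long shifts in the ChIP library and 1.33 times in the input.

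**Figure D1:**
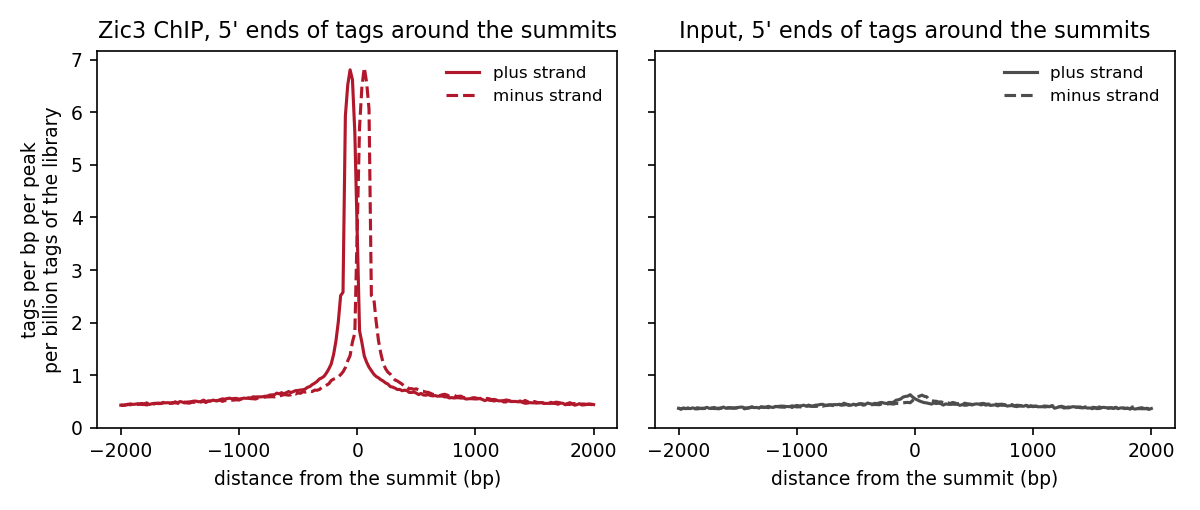
Mean density of tag 5′ ends, in tags per bp per peak per 1000000000 tags of the library, against distance in bp from the summits of the 23918 peaks; solid lines are plus-strand and broken lines minus-strand tags. The ChIP strands peak 60 bp before and 60 bp after the summit, and the input rises only slightly on the same scale.

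At the 23918 deposited peaks, the ChIP library held more tags than the input in most cases. An adjusted p under 0.05 in the exact binomial test was reached at 21892 peaks, or 91.5%, and 0 of these had more input. At 10341 peaks, or 43.2%, ChIP was also at least 5-fold above input. These 10341 include all 496 peaks with 0 input tags, whose fold is set by the 0.5 tag added, and 9845 peaks with an input tag. Among peaks with an input tag, at least 10-fold was reached by 3023 and at least 20-fold by 586. The median fold was 4.47, with a 95% interval from order statistics over peaks of 4.43 to 4.49 and quartiles of 3.16 and 7.23. The median peak held 28 ChIP tags and 5 input tags within 200 bp of its summit. The 2026 peaks that missed the threshold are not shown to lack binding. The peaks were called for ChIP excess in these same tags, so the direction was set by their choice, and the counts describe the size of the excess rather than test it anew. Of 22015 positions 10 kb downstream of the summits, kept because no deposited peak lay nearby, 0 had an adjusted p under 0.05 in the same test and 1.88% had an unadjusted p under 0.05. That choice left out places where the peak caller had found an excess. The adjustment was also made within each set of positions. Where few positions are raised it demands a much smaller unadjusted p than at the peaks. The 0 calls are therefore not at the same threshold as the 91.5% of peaks. With all 23918 downstream positions kept, 166 had an adjusted p under 0.05, or 0.694%. The fold of the summed tags was 0.980 at the positions away from peaks and 5.45 at the summits. The count of peaks at least 5-fold above input depended on the settings: it was 14858 within 100 bp of the summit, 3954 within 500 bp, and 3003 with 5 tags added to each count. The median fold was 6.29, 2.89 and 2.69 in these cases.

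Tags near summits were a small part of each library. Of the ChIP tags, 5.47% lay within 200 bp of a summit, with a Clopper-Pearson 95% interval of 5.46 to 5.48%. Of the input tags, 1.00% lay there, with an interval of 0.999 to 1.01%. Around the 22015 positions 10 kb away, which cover 8.82 Mb against 9.59 Mb around the summits, the shares were 0.534% for ChIP, with an interval of 0.530 to 0.537%, and 0.545% for input, with an interval of 0.540 to 0.549%. At the 22015 summits that gave these positions, input tags were 1.68 times as many as 10 kb away. Over all summits they were 2.39 times the genome average of 2.27 per window. Here and below, that average is taken only over 1 kb bins that hold an input tag, 2281 Mb together.

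The 15 peaks with the highest deposited fold lay on 12 chromosomes, and ChIP exceeded input by 24.5-fold or more at each. The highest deposited fold, 147.21, belonged to a peak at chrX:44316182-44317468. It held 222 ChIP tags and 3 input tags, a 52.2-fold excess with a 95% interval of 20.5 to 297 and an adjusted p of 4.25e-50 in the exact binomial test. At chr17:72786812-72787327, with a deposited fold of 129.92, there were 155 ChIP tags and 2 input tags, a 51.0-fold excess with an interval of 17.3 to 530. A peak at chr5:44156802-44158117 held the most ChIP tags of the 15, with 335 against 7 in the input, a 36.7-fold excess with an interval of 18.8 to 98.4. A further peak on the same chromosome, at chr5:12878651-12879642, held 235 against 5. The lowest fold of the group was at chr19:11366495-11367098, with 134 against 4 tags, a 24.5-fold excess with an interval of 10.5 to 102. The highest point estimate was 86.2-fold at chr13:91343051-91343980, where 157 ChIP tags stood against 1 input tag and the interval ran from 22.8 to 5120. The intervals of all 15 overlapped, so their order by fold over input is not resolved by these counts. Chromosome 3 gave a pair of these peaks, at chr3:18815890-18816767 with 210 ChIP tags and 3 input tags and at chr3:53737931-53738628 with 229 and 5. Chromosome 14 gave a pair as well, at chr14:48369520-48370248 with 186 and 4 tags and at chr14:33720828-33721711 with 180 and 3. The remaining peaks were chr1:41075603-41076498 with 198 and 3 tags, chr6:5275047-5275624 with 162 and 3, chr16:92894966-92895683 with 160 and 3, chr15:90905578-90906352 with 168 and 4, and chr2:172235698-172236389 with 215 and 6.

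**Figure D2:**
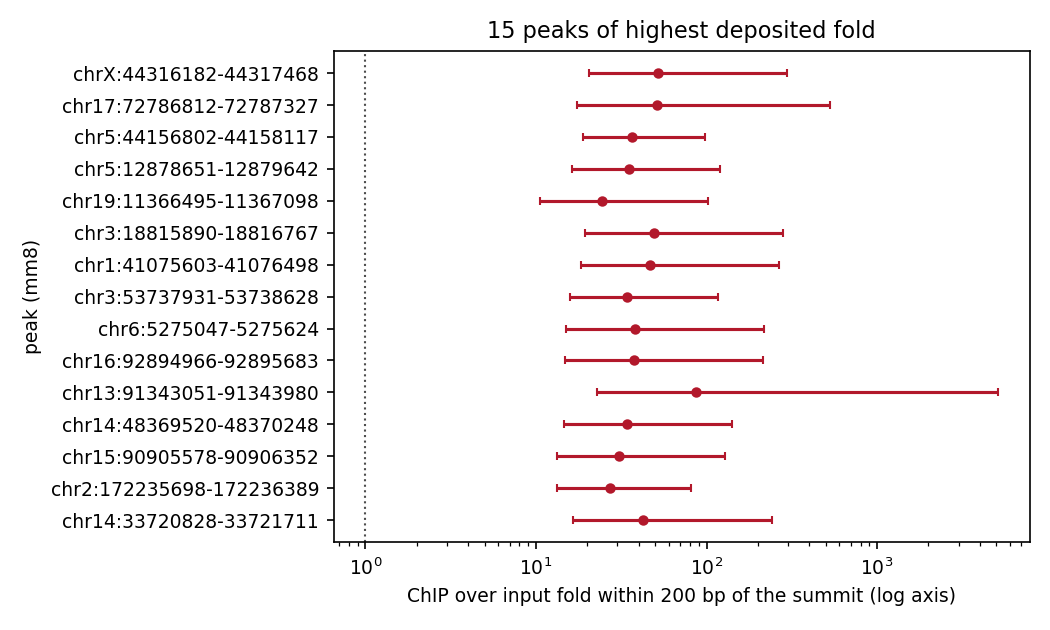
Fold of ChIP over input within 200 bp of the summit, on a log axis, for the 15 peaks with the highest deposited fold, in that order; points are ratios with 0.5 tag added and bars are exact 95% intervals of the ratio without it. All bars lie above 10-fold and overlap one another, and that of the chr13 peak, with 1 input tag, reaches 5120.

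At the other end, the 5 peaks with the lowest fold over input had no excess that the test could detect within 200 bp of the summit. They were chr9:64926137-64926964, with 26 ChIP tags and 21 input tags and a fold of 1.01, chr11:116014738-116015494, with 12 and 9 tags and a fold of 1.08, chr8:91842864-91844235, with 24 and 18 tags and a fold of 1.09, chr14:102231661-102232876, with 22 and 16 tags and a fold of 1.12, and chr10:67531859-67532440, with 16 and 11 tags and a fold of 1.18. Their adjusted p-values in the exact binomial test ran from 0.801 to 1, while their deposited folds ran from 4.08 to 5.32. Over wider stretches 4 of the 5 passed the threshold, all but the chr11 peak. Over the whole deposited interval the folds of these 4 were 1.75 on chr9, 2.36 on chr8, 2.23 on chr14 and 3.98 on chr10, with adjusted p-values of 3.31e-05 to 0.0209 in the exact binomial test. The chr11 peak had a fold of 1.72 there and an adjusted p of 0.0846 in the same exact test.

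The input count was 0 at 496 peaks, or 2.07%, and a fold over input has only a lower limit there. Among these, the peaks with the most ChIP tags were chosen after their values were seen. The first was chr6:102712419-102713123, with 142 ChIP tags, and its exact 95% interval started at 31.2-fold. The next were chr7:66161861-66163060 with 137 tags and a lower limit of 30.1-fold, chr18:27869389-27870059 with 117 tags and a lower limit of 25.6-fold, and chr18:54652971-54653532 with 110 tags and a lower limit of 24.1-fold. Set against 3 input tags, the ratio of the chr6 peak was 38.8, which leaves out the counting error of its ChIP tags.

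Several of the peaks with the most tags in the deposited list had raised input as well, and they too were singled out after their values were seen. The peak at chr17:39451014-39456957 spanned 5944 bp and held 7333 ChIP tags, or 0.0466% of the library, and 962 input tags. The ChIP excess over the whole interval was 6.25-fold, with a 95% interval of 5.85 to 6.70, and input density there was 28.6 times the genome average. In its 28 inner windows of 200 bp the fold ran from 3.74 to 9.66. In the 9 kb on each side, from 1 kb outwards, the fold was 1.29. The peak at chr11:3039417-3048969 was the longest of the list, at 9553 bp with 3243 tags, and its fold at the summit was 4.05 with a 95% interval of 3.06 to 5.51. At a neighbouring peak, chr11:3075502-3080366 with 776 deposited tags, the fold at the summit was 1.32, with an interval of 0.942 to 1.88 and an adjusted p of 0.114 in the exact binomial test. At a further neighbour, chr11:3095365-3100206 with 721 deposited tags, it was 1.59, with an interval of 1.097 to 2.37 and an adjusted p of 0.0169 in the same test. A peak at chr5:118695696-118698570 held 689 deposited tags, with 261 ChIP tags and 8 input tags at its summit and a 25.2-fold excess.

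Excess over input followed the deposited score, which the peak caller computed from the same tags, so that a rise was set by how the peaks were ranked and only its size is described here. In the lowest decile of the deposited score, 67.9% had an adjusted p under 0.05, 15.2% were also at least 5-fold above input, and the median fold was 2.96. In the highest decile these values were 100%, 98.4% and 12.3. The median number of input tags was 5 in every decile, and the median number of ChIP tags rose from 18 to 84. The deposited false discovery rate of the peaks ran from 0 to 0.61%, with a median of 0.04%, and 221 peaks had a rate of 0.

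**Figure D3:**
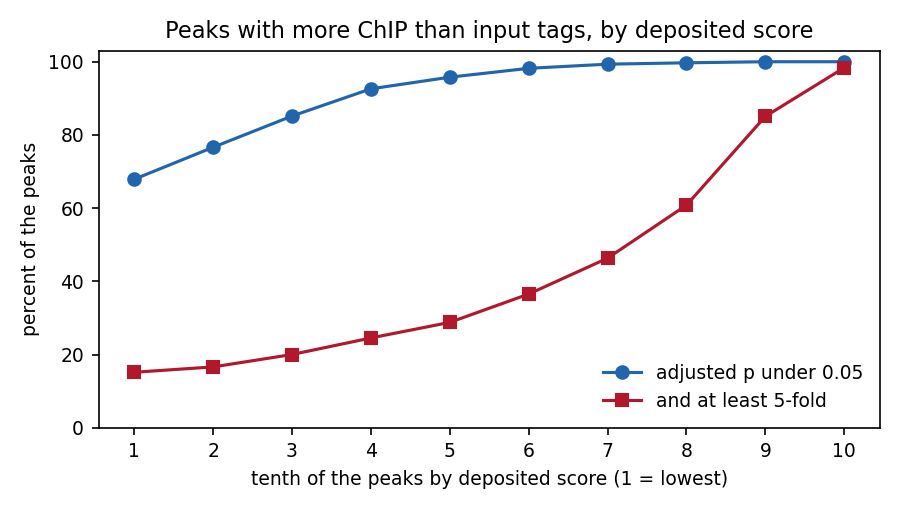
Percent of the peaks with an adjusted p under 0.05 (circles) and with at least 5-fold more ChIP besides (squares), on the vertical axis from 0, against the decile of the deposited score. The score was computed from the same tags; the circles rise from 67.9% to 100% and the squares from 15.2% to 98.4%.

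Enriched windows found without the peak list fell almost entirely within deposited peaks. Among 200 bp windows, 8274 had at least 5-fold more ChIP tags with an adjusted p under 0.05 in the exact binomial test, in 6863 merged regions. Of these windows, 8265, or 99.9%, overlapped a deposited peak, and 9 did not. Windows with at least 5-fold more input numbered 0. With no minimum fold, 8517 windows had more ChIP and 30 had more input, and all 30 lay on the mitochondrial chromosome. At an unadjusted p under 0.05, ChIP was higher in 50685 windows and input in 28944. The windows recovered 6623 peaks, or 27.7%, among them 99.0% of the highest decile by score and 0.460% of the lowest. The single-window test thus called far fewer regions than the peak list holds, mostly those of high score. It used the same tags as the peak caller at a stricter threshold, so the high overlap is not independent support for the list.

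Peaks were unevenly spread over the chromosomes. The genome had 1851 peaks per 1000000 input tags, and chromosome 19 had 2578, with an exact Poisson 95% interval of 2398 to 2767, or 1.39 times the genome. Chromosome 11 followed with 2279, with an interval of 2175 to 2386. The lowest autosomes were chromosome 3 with 1536, with an interval of 1448 to 1629, and chromosome 1 with 1555, with an interval of 1477 to 1635. Chromosome X had 439 peaks, or 1485 per 1000000 input tags, with an interval of 1349 to 1631 and 0.802 times the genome. Among the 50% of peaks with the higher deposited folds, chromosome X was instead above the genome, at 1.28 times. Divided by ChIP tags instead, the differences were smaller: chromosome 19 had 1816 peaks per 1000000 ChIP tags, with an interval of 1689 to 1949, or 1.20 times the genome, and chromosome 11 had 1782, with an interval of 1700 to 1866. Chromosome X had 1373, or 0.904 times the genome, above chromosome 1 with 1350 and chromosome 3 with 1343. The deposited fold was read as taken against the local background, and input density on chromosome X was 0.352 of that on the median autosome. Chromosome Y had 1 peak over 2275 input tags.

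**Figure D4:**
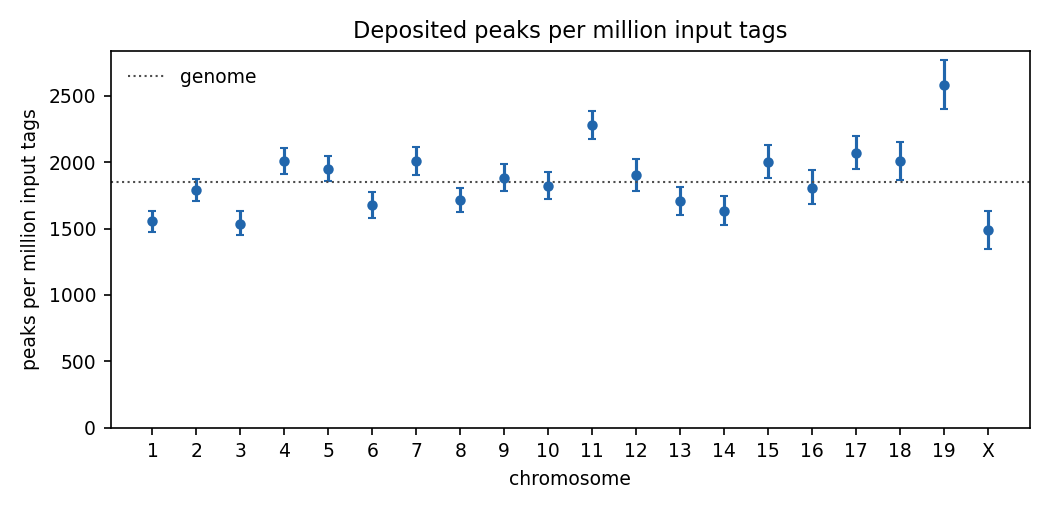
Deposited peaks per 1000000 input tags for each autosome and chromosome X, on a vertical axis from 0; points are the values, bars are exact Poisson 95% intervals and the dotted line is the genome at 1851. Chromosome 19 stands highest at 2578 and chromosome X lowest at 1485; divided by ChIP tags, chromosome X is not the lowest.

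Summits lay closer together than random positions. Of 23897 pairs of neighbouring summits, 27.4% were under 10 kb apart, against a mean of 12.2% and a highest value of 12.6% in 100 random sets of input tag positions. The median distance was 33241 bp, against a mean of 59478 bp in the random sets. The densest stretches were picked after their values were seen. Between chr4:146919344 and chr4:147013528 there were 19 summits in 94.2 kb, of which 18 had an adjusted p under 0.05 in the exact binomial test, with folds from 1.84 to 14.6. Between chr4:132231240 and chr4:132329621 there were 16 summits, of which 16 passed, with folds from 2.54 to 19.8. A stretch on chromosome 19, from chr19:46488875 to chr19:46587091, also had 16 summits, of which 15 passed. The stretch from chr1:88271584 to chr1:88363080 had 16 summits of lower folds, with a median of 2.71, and 10 of them passed. Input was also raised in these 4 stretches, at 1245 to 1546 tags per 100 kb against 466 on the median autosome, and over the whole stretches the fold was 1.49 to 1.59. Other stretches with 16 summits had 1532 input tags per 100 kb on chromosome 17, 1255 on chromosome 7 and 2056 on chromosome 8. The whole-stretch fold of that on chromosome 8 was 1.43. By the number of ChIP tags in excess of input within 200 bp of summits, the leading 100 kb bin was chr17:29100001-29200000, with 12 summits, 841 ChIP tags and 80 input tags near them. In the bin chr14:53300001-53400000, 6 summits held 703 ChIP tags and 39 input tags, a 14.8-fold excess.

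The background of the libraries also differed along the chromosomes. Over 100 kb bins, the median ratio of ChIP to input, scaled by library totals, was 1.15 on chromosome 19, 1.08 on chromosome 18, 0.904 on chromosome 2 and 0.854 on chromosome X. In segments of 10 Mb, the ratio was above the autosomal median at the start of all 19 autosomes, by 1.07 times or more. It reached 1.54 at the start of chromosome 12 and 1.58 at the start of chromosome 16. On chromosome 19 it lay between 1.09 and 1.44 in all 6 segments. The fold over input of a peak in such a region includes this factor.

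**Figure D5:**
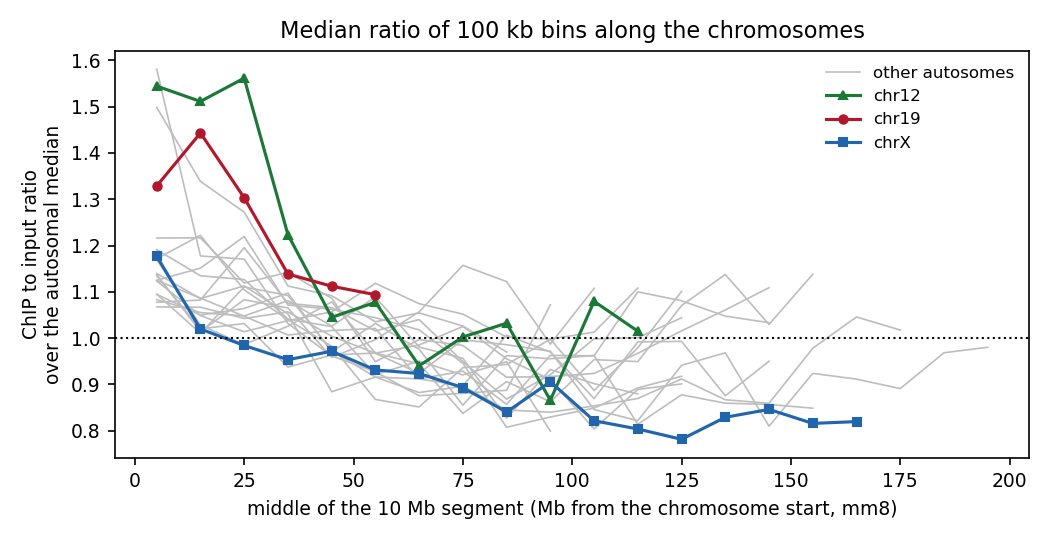
Median ratio of ChIP to input over 100 kb bins in each 10 Mb segment, relative to the median of autosomal bins, against the position of the segment in Mb; coloured lines are chromosomes 12, 19 and X and grey lines the other autosomes. All lines start above 1, and most fall along the first part of the chromosome, from 1.54 on chromosome 12 and from 1.18 on chromosome X.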

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

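The tests of the chromosome 19 ratio on bins without peaks, on bins matched in tag density and on segments were set before their values were seen, and the tests of the raised input, of the chr17 region and of position on chromosome 19 were chosen afterwards. No group in the design gives a biological explanation for these patterns; the explanations below that concern the cells, such as binding and copy number, were tested only as stated.

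Outside the deposited peaks, 9 windows of 200 bp had at least 5-fold more ChIP than input. In 5 of them the input held 0 tags against 18 to 20 ChIP tags, so that their fold is set by the 0.5 tag added, and its exact lower limits were 3.61 to 4.05. The 9 windows drew attention as ChIP excess in tags that the peak comparisons leave out. At an adjusted p under 0.05, some of the 8274 windows called can be false, and these 9 are a small part of them. Whether they hold binding was not tested. The clearest was chr10:127844401-127844600, with 44 ChIP tags and 3 input tags, a 10.4-fold excess and an adjusted p of 3.27e-05 in the exact binomial test, 31428 bp from the nearest deposited peak. The next was chr8:73560001-73560200, with 29 ChIP tags and 2 input tags and an adjusted p of 0.00846, and the other 7 had adjusted p-values of 0.0163 to 0.0451.

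The ratio of ChIP to input differed between chromosomes and was highest on chromosome 19. In 100 kb bins with no peak within 50 kb, chromosome 19 was still 1.28 times the other autosomes, with a 95% interval of 1.23 to 1.34, and matching those bins in 10 classes of summed tags left 1.27 times, so neither binding at the deposited peaks nor tag density accounts for it. The lowest 10 Mb segment of chromosome 19 was 1.09 times the autosomal median, with an interval of 1.06 to 1.11, as a different copy number in the cells of the libraries would require, but the highest was 1.44 times, with an interval of 1.39 to 1.48, where a copy number of the whole chromosome alone would give a single ratio. Distance from the start of the chromosome does not account for the whole excess. Over the other autosomes at the same distance from the start, the 6 segments ran from 1.07 to 1.33 times. Their median was 1.14, with a 95% interval above 1. Distance from the far end was not matched, so an effect of both ends of a short chromosome remains open. The last segments of the other autosomes ran from 0.799 on chromosome 17 to 1.14 on chromosome 4, relative to the autosomal median. A part played by copy number stays open, because all 6 segments lay above the autosomal median. It is not shown either, because the segments were unequal and 46 of 243 segments on other autosomes were as high as the lowest of chromosome 19.

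The input library was itself raised at the summits. If ChIP DNA had been carried over into the input, the excess would grow with the ChIP tags, which were 5.11 times as many in the highest decile of peaks by score as in the lowest. The input excess was only 1.39 times as large, with an interval of 1.24 to 1.57. The score is computed against the local input, so ranking by it can lower the input excess of the highest decile. Broad regions of raised copy number or mappability would raise the surroundings equally, but input within 100 bp was 1.47 times that 1 to 2 kb away, with an interval of 1.46 to 1.49. Broad regions fall short as the whole cause, and so does carry-over, within the limit of the ranking by score. Easier shearing of open chromatin remains open and was not tested.

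The tag-dense region at chr17:39451014-39456957 held the most ChIP tags of any deposited peak. Extra copies of a region that the build holds once would raise both libraries equally, but ChIP was 6.25-fold above input, so copies alone do not account for the excess, although the input stood at 28.6 times the genome average. With a single binding site the fold would return to that of the surroundings away from it, but among 17 windows more than 1 kb from the summit the lowest fold was 4.04, with an interval of 2.85 to 5.98, against 1.29 outside the region. ChIP tags filled 61.7% of the positions and strands in the region, so its folds are understated, and allowing for filled positions raised the overall fold to 9.33. Within 500 bp of the summit the fold was 6.14, against a median of 6.18 over the 28 inner windows. A single site held in each of many copies would also give a fold that falls away from it. These windows therefore argue against that as well, in this 1 ChIP library. Binding along the whole of each copy remains open and was not tested.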

How the results depend on the processing

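The backgrounds at positions downstream of the summits, the thinned input, the whole intervals for the tag share, the exclusion of chromosomes, the division by ChIP tags and all settings of the summit spacing were chosen after the result was seen. Counting all tags or at most 2 per position changed nothing by construction, because no tag repeats a position. The settings listed for genes, gene lists and sequence motifs were not run, and with 1 library per group none was left out. No paired analysis was possible because each group has 1 library. The cause of a shift was not tested unless the setting itself gives it, as fewer peaks or wider windows do.

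The number of peaks with an adjusted p under 0.05 stayed within 1.5 times of 21892 except where peaks were removed or positions changed, with 11736 of 11959 peaks in the 50% of higher deposited fold and 4223 of 4258 with input at or below the genome average, and with 0 at downstream positions away from peaks and 166 at all downstream positions. The number at least 5-fold above input was 3954 within 500 bp, 3003 with 5 tags added, 3874 with low input, 0 downstream away from peaks and 117 at all downstream positions. The adjustment was made anew within each set of positions, so the downstream positions met a stricter unadjusted threshold. The median fold was 6.29 within 100 bp, 2.89 within 500 bp, 3.95 over whole intervals, 4.76 when scaled by tags outside peaks, 4.74 when scaled by the median 10 kb bin, 4.10 with 1 tag added, 2.69 with 5, 6.65 in the 50% of higher deposited fold, 9.03 with low input, 3.87 against the larger of the window and the 5 kb background, 4.28 with the input thinned to 50%, and 0.820 at both sets of downstream positions. The value of 0.820 is what equal tag counts in both libraries give, because the ChIP library is larger, so it does not show a lack of ChIP tags. The fold of the summed tags at the positions away from peaks was 0.980.

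The share of ChIP tags near summits was 7.70% within 500 bp, 5.41% with tags not moved, 3.49% for the 50% of higher deposited fold and 7.45% over whole intervals. For input it was 2.27%, 0.428% and 1.78% at 500 bp, in those 50% and over whole intervals. Windows with more ChIP numbered 5317 at 10-fold and 4780 at an adjusted p under 0.001, and those with more input 13 at 3-fold and 17 with 500 bp windows. The share of enriched windows overlapping a peak was 99.6% with 500 bp windows and 99.98% at an adjusted p under 0.001. Chromosome X rose to 1.28 times the genome in the 50% of higher deposited fold, and with peaks divided by ChIP tags chromosome 19 was 1.20 times and chromosome X 0.904 times. Neighbouring summits under 5 kb apart made up 18.2%, those under 50 kb 59.1%, and those under 10 kb within the 50% of higher deposited fold 14.8%, against a mean of 6.21% at random.

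For the 15 peaks of highest deposited fold, all 226 values over 16 settings kept an adjusted p under 0.05 and at least 5-fold, from 12.7-fold to 120.1-fold where the input held a tag; 5 of the values had 0 input tags. Among the peaks of lowest fold, the chr9 peak went below 1 with 5 tags added, at 0.978, and with the ChIP library thinned, at 0.953. The chr11 peak did so with 5 tags added, at 0.996, and with tags not moved, at 0.993, and the chr14 peak with the input thinned to 50%, at 0.879. Adding 5 tags moves a fold towards that of equal counts, which is below 1 because the ChIP library is larger. A fold near 1 therefore drops under that setting by construction. In the other direction, 4 of these 5 peaks gained an adjusted p under 0.05 both within 500 bp, with folds of 1.66 on chr9, 1.63 on chr8, 2.02 on chr14 and 1.86 on chr10, and over the whole interval, with 1.75, 2.36, 2.23 and 3.98. Depth set how many peaks passed: thinning the input to 50% of its tags left 15931 with an adjusted p under 0.05, and thinning the ChIP library to the input total left 21146.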

Other observations

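The tests of the fall along the chromosomes on bins without peaks and of neighbouring peak strength under 10 kb were set before their values were seen; the class of 1 to 10 kb and the division at 30 Mb were chosen after values had been seen.

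The ratio of ChIP to input fell from the start of most chromosomes, but on some it rose again further along. It was higher in the first 30 Mb than beyond on 18 of 19 autosomes, with chromosome 11 the exception at 0.992 times, and the median over autosomes was 1.15 times; no test is given, because the division followed from the values. On chromosome 12 it was 1.51 times and on chromosome X 1.25 times. Tags per 100 kb in the first 30 Mb were at a median over autosomes of 0.781 times those beyond for ChIP and 0.667 times for input, with ChIP higher there on chromosomes 14, 16 and 17, at 1.16, 1.64 and 1.15 times, and input on chromosome 16, at 1.19 times. The hypothesis that deposited peaks produce the fall was not borne out, since in bins without peaks the median was 1.20 times, with values of 1.01 to 1.67 over the 19 autosomes. A cause was not found.

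Neighbouring peaks may share a local strength of binding. Over pairs of neighbouring summits, Spearman's rho of the ChIP tags was 0.122 for 6545 pairs under 10 kb apart, 0.0618 for 11456 pairs 10 to 100 kb apart and 0.0513 for 5896 pairs over 100 kb apart. Each had a permutation p of 0.000999, the smallest that 1000 permutations can give, and an adjusted p of 0.000999 over the 4 comparisons; peaks are not independent replicates. Without pairs under 1 kb apart, whose windows can overlap, a class added afterwards, rho was 0.121 for 5502 pairs. The nearest class exceeded the farthest by 0.0703, between the limit of 0.1 set for the hypothesis and that of 0.05 set against it, so the hypothesis stays undecided.

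Mitochondrial tags were a smaller share of the ChIP library, at 0.0110% with a Clopper-Pearson 95% interval of 0.0105 to 0.0116%, than of the input, at 0.0274% with an interval of 0.0265 to 0.0283%. The 30 windows with more input than ChIP all lay there.

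The deposited false discovery rates did not fall steadily with the score. Their median was 0.26% at scores of 50 to 60, 0.02% at 80 to 120, 0.37% at 800 to 1600 and 0% above 1600. If the rates come from exchanging ChIP and input, they can be multiplied by the number of peaks at or above the score. They then imply about 105 exchanged calls at the lowest score of 50. A rate above 0 persisted up to a score of 1294. Between scores of 120 and 1600 the implied number stayed at a median of 1.9 to 2.0 per score class. On that reading, the rate rose there because fewer peaks lay at or above the score, not because more exchanged calls did.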
